A study of Mus musculus with 11 samples.

How the data were processed

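The deposited file of each array holds the spot intensity as scanned and the processed signal of Agilent Feature Extraction 9.5.3.1 (protocol GE1-v5_95_Feb07, array design 014868), which is, per the file headers, an intensity after background subtraction and detrending within that array and is not scaled between arrays. The authors also deposited a table of log2 values for 33322 distinct probes. Per the submitters' processing notes that table was made with RMA, and its settings are not stated. Its 11 columns have nearly the same distribution, with medians from 7.707 to 7.712. Each column lay closest to the processed signal of its own array, with a correlation across probes of at least 0.9. Per the labels' protocols, liver RNA was purified on Qiagen columns, amplified with a linear amplification kit and labelled with Cy3 alone.

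The values used here are log2 of the processed signal minus the 75th percentile of the same array over its non-control spots. Spots marked as outliers by Feature Extraction and control spots were left out, and repeated spots of a probe were averaged. A probe was tested if it was well above background on every array of at least 1 of the 4 groups, which kept 27151 of 41174 distinct probes. Gene symbols came from the supplied RefSeq table, through an accession for 23374 probes, through the symbol in the file for 6733 and through a synonym for 2919. A further 1845 probes had a symbol in the file only, and 6303 had none. A gene with several tested probes, as for 6351 genes, was read from the probe with the highest mean over all 11 arrays. Positions of probes are those in the files, on mouse build mm8. After 52 features without a value in some group were left out, 18226 features remained, of which 15945 were genes with a symbol.

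Genes were tested with limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8) for reading. Each of the 4 groups had its own coefficient, all 11 arrays shared 1 estimate of the spread (7 residual and 2.38 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the 15945 genes, with a threshold of 0.05. The contrasts were mutant against control over both days with equal weight, at day 0 and at day 2, the difference between these, and day 2 against day 0 in each genotype. The 24 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, on the 17951 features with a value on every array, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Where no array of a group was well above background for a gene, its level was put no lower than the dimmest value above background on each of those arrays, and the fold is given as at least that ratio. The fitted difference of such a gene is not read as a size.

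The values, the filter, the contrasts, the tests, the 24 lists and the rule for naming genes were chosen before the data were examined. Over both days the rule took the 12 largest fitted rises and the 12 largest fitted falls among genes past the threshold in which every mutant array lay on the same side of every control array of its day. In the other contrasts it took 8 of each. Sex-linked genes and names of clones or predicted genes were passed over. It also took up to 4 members of each list with the smallest p-value, and 19 genes whatever their values. For the difference between the days, every mutant array had to lie on the same side of every control array on at least 1 day, in the direction of that difference.

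Replicates 1, 2 and 3 of each group lie on slides 1, 2 and 3. Slides 1 and 2 hold all 4 groups, and slide 3 has no day 0 control. Each group has the same array position on every slide, so array position and group cannot be told apart. For the control and mutant arrays of day 2, the deviations from the group means were correlated across genes. The values were 0.294, 0.239 and 0.286 between arrays of the same number and from -0.232 to -0.0377 between the others. The numbers therefore pair these arrays. Arrays of the same number from different days share a slide as well, and correlated from -0.0447 to 0.132. A slide effect common to all 4 groups is therefore little seen, and what pairs the day 2 arrays was not tested. For the lists that passed, means within slides are given at least where a slide differed from the pooled mean by over 1.5 times, and values with slide as a block at least where it changed a call or moved a count by that much. The share of called genes with the same direction on each slide was computed first and dropped, as simulated null data gave nearly the same share. In its place, genes were called without a slide and their direction was then read on that slide, a check chosen after the data were seen.

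The steps were run on simulated values for 15730 genes with known changes. Over both days 69 of 100 genes changed by 1 log2 unit and 92 of 100 changed by 2 were recovered, with 7 unchanged genes called. At day 0 these numbers were 27, 73 and 6, and at day 2 they were 42, 79 and 8. With the change made in the mutants of day 2 alone, the day 2 contrast recovered 36 and 82 with 2 unchanged genes called, and the difference between the days recovered 5 and 58 with 2 unchanged genes called. The age contrast recovered 22 and 83 in controls with 3 unchanged genes called, and 35 and 88 in mutants with 5. A list shifted by 1 log2 unit had an adjusted p of 1.62e-47 in camera, and none of 23 other lists was called. The genes were simulated independently, so this check cannot show how often camera calls lists whose genes vary together.

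The alternatives were quantile normalization, normexp background treatment with either scaling, the authors' RMA table, no filter on dim probes, a filter on all 11 arrays, the mean over a gene's probes, slide as a fixed or a random block, a trended and robust variance prior, array weights and pup sex as a covariate. Fits without a day term, with additive terms, on the compared groups alone and without each array in turn were also run, and all were planned before the data were examined. Pup sex was read from Xist and from 4 Y-linked genes, as the labels do not give it. Probes without a symbol were fitted and are not reported by name. Isoforms and alleles were not analysed here, and single values of a few list members are not reported here.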

Results

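Liver RNA from 11 newborn mice of a hybrid strain background was measured on Agilent whole mouse genome arrays in 1 colour. Mutant pups carried a Cre recombinase under the alpha-fetoprotein promoter together with a Rosa26 allele in which Cre removes a stop cassette, so that the cells make NICD, the active intracellular part of Notch. Control pups carried the Rosa26 allele alone. No group carried Cre alone, so effects of the Cre transgene and of NICD cannot be told apart. There were 2 controls and 3 mutants taken at birth, called day 0, and 3 controls and 3 mutants taken on day 2. The 75th percentile of the signal ran from 607.72 to 1301.5 between arrays, and from 63.3% to 68.6% of spots were well above background. Arrays of the same group correlated across genes at 0.983 or more, except that mutant day 0 replicate 3 correlated at 0.956 and 0.954 with the other day 0 mutants. Of 15730 genes, 470 lay at least 2-fold below and 604 at least 2-fold above all other arrays on that array, while no other array had more than 66 in either direction. Xist and Y-linked genes showed 2 males among the day 0 controls, 3 females among the day 0 mutants, and 1 male and 2 females in each group of day 2, so sex and genotype coincided at day 0. The number of arrays limits the precision, and the p-values measure only the spread between these samples, which are known to be separate pups only from their labels.

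Notch1 is the gene whose intracellular part the mutants express. Its signal, in log2 units relative to the 75th percentile of the array, was -2.01 ± 0.23 (SD, n = 2) in day 0 controls, -2.03 ± 1.13 (SD, n = 3) in day 0 mutants, -2.28 ± 0.09 (SD, n = 3) in day 2 controls and -1.87 ± 0.08 (SD, n = 3) in day 2 mutants. The difference over both days was 0.20 ± 0.33 (SE, adjusted p = 0.753). The spread was by far the widest in the day 0 mutants, the group that holds the array lying apart (replicate 3). At day 2 the mutant mean lay above the control mean by more than the SD of either group. The result over both days therefore does not show that Notch1 was unchanged. The probe lies on chromosome 2 at 26281261 to 26281319 (mm8), and whether it reads the transgene is not known, so its level does not check the labels. Notch2 and Notch3 did not pass either, with differences of 0.29 and 0.20 and adjusted p of 0.378 and 0.543.

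The first comparison asked how gene expression in the newborn liver differs between 6 mutants and 5 controls, over both days with equal weight. Several targets of Notch rose. Nrarp, a feedback inhibitor of Notch (chromosome 2, 25004527 to 25004586), was 13.4-fold higher in mutants at day 0 and 14.2-fold higher at day 2, a mean log2 difference of 3.79 ± 0.20 (SE, adjusted p = 1.12e-05). Sox9, a transcription factor of bile duct cells (chromosome 11, 112601784 to 112601843), was 10.8-fold and 35.7-fold higher, a difference of 4.30 ± 0.19 (SE, adjusted p = 5.52e-06). The Notch-dependent repressor Hey1 was 5.52-fold and 13.3-fold higher (adjusted p = 8.65e-05), and its relatives Heyl and Hes1 rose by 2.35 ± 0.40 and 1.78 ± 0.27 (SE, adjusted p = 0.00435 and 0.00256). Heyl was no higher on mutant day 0 replicate 3 (-1.44) than in the day 0 controls (-1.29 and -0.93), while the other 5 mutants lay above every control of their day. Ccnd1, which encodes cyclin D1, was 6.09-fold and 7.99-fold higher (2.80 ± 0.27 SE, adjusted p = 0.00018).

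Of 23 measured Notch target genes, 10 rose and 13 did not pass, and 12 rose and 1 fell when adjusted over the list alone. Their mean difference was 1.11 log2 units (camera, adjusted p = 3.69e-07, and 0.143 with an estimated correlation), 1.20 and 0.81 within slides 1 and 2 and 1.11 with slide as a block. Of 26 receptors, ligands and other parts of the Notch pathway, 4 rose and 22 did not pass, and 4 rose when adjusted over the list alone. Their mean was 0.22 (adjusted p = 0.00884, and 0.162 with an estimated correlation), 0.22 and 0.15 within the slides and 0.14 after normexp treatment with the same scaling. Among them Notch4 and the ligand Dll1 rose by 0.61 ± 0.12 (SE) and 0.97 ± 0.22 (SE). The ligand Jag1 rose by 0.82 ± 0.22 (SE, adjusted p = 0.0328), and passed in 14 of 25 other settings.

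**Figure D1:**
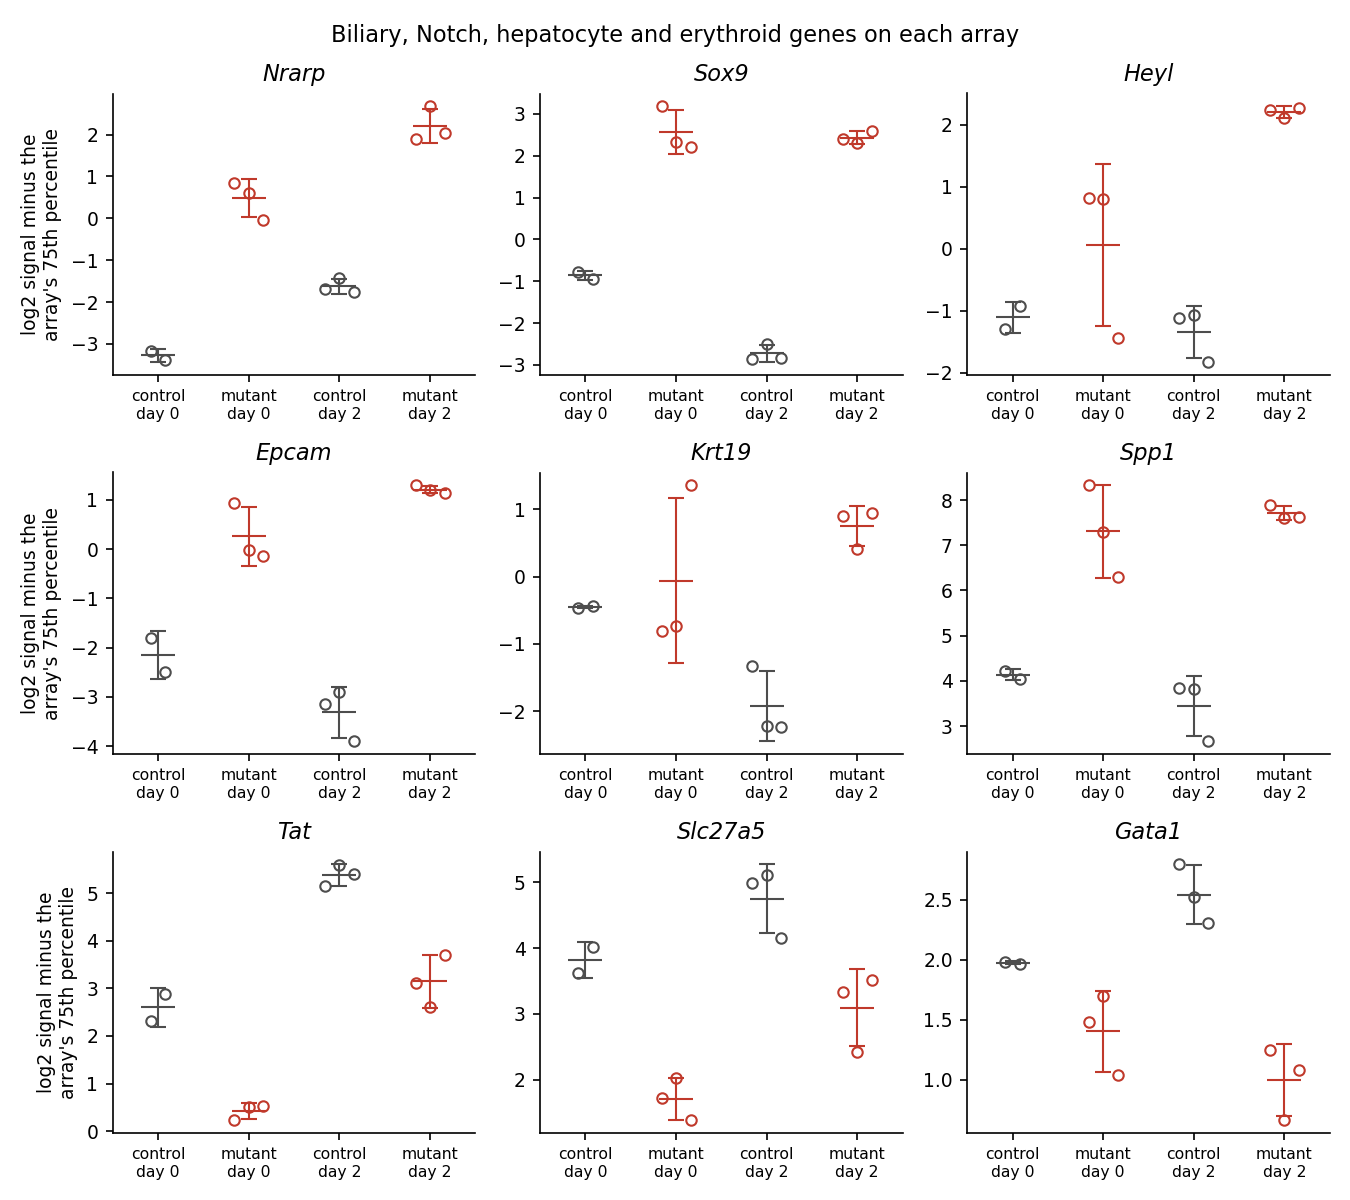
Signal of 9 genes on each of the 11 arrays, in log2 units relative to the 75th percentile of the array, by genotype and day; circles are arrays, dashes are group means and bars are SD. Nrarp and Sox9 lay higher in all 6 mutants than in the 5 controls, Tat and Slc27a5 lay lower than in the controls of the same day, and Heyl and Krt19 of 1 day 0 mutant (replicate 3) lay apart from the other day 0 mutants.

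Many genes of bile duct cells rose as well. Spp1, which encodes osteopontin, was 9-fold higher at day 0 and 19.2-fold higher at day 2 (3.72 ± 0.36 SE, adjusted p = 0.000188), and Epcam, an adhesion protein of duct and progenitor cells, was 5.31-fold and 22.9-fold higher (3.46 ± 0.26 SE, adjusted p = 4.51e-05). The receptor Ddr1, the ciliary protein Dcdc2a and the tight junction protein Cldn7 rose by 3.07, 3.82 and 2.99 log2 units, with adjusted p of at most 3.44e-05. Of 37 measured duct genes, 21 rose, 4 fell and 12 did not pass, and 23 rose and 6 fell when adjusted over the list alone. Their mean was 1.08 (camera, adjusted p = 1.65e-09, and 0.0725 with an estimated correlation), 1.10 and 0.94 within slides 1 and 2 and 1.10 with slide as a block. The duct keratin Krt19 rose by 1.53 ± 0.40 (SE, adjusted p = 0.03) and passed in 14 of 25 other settings, and Krt7 rose by 0.77 ± 0.17 (SE, adjusted p = 0.0143).

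Upk3a, a protein of the urothelial surface (chromosome 15, 84849155 to 84850056), was at least 322-fold higher at day 0 and at least 50.5-fold higher at day 2 (adjusted p = 3.58e-05). The sodium channel subunits Scnn1g and Scnn1b were at least 26.5-fold and at least 4.28-fold higher at day 0 and at least 29.5-fold and at least 20.1-fold higher at day 2. The neurotrophin receptor Ntrk2 was at least 14.5-fold and at least 68.6-fold higher. The matrix protein Spon1 was 15.7-fold and 88.7-fold higher, with 1 of 3 day 2 controls above background. Wfdc3, Tmem145 and Fmo2 rose by 5.02 to 5.97 log2 units, and the 2 probes of Wfdc3 differed in direction. Rhov, Rasgrf1 and Akr1cl were at least 12.3-fold, 7.12-fold and 3.74-fold higher at day 0 and at least 15.2-fold, 51.7-fold and 23.1-fold higher at day 2, and Rflna was 19.8-fold and at least 63.9-fold higher.

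Other genes fell. The C-type lectin Clec2h (chromosome 6, 128642126 to 128642185) was at least 11.5-fold lower at day 0 and at least 7.90-fold lower at day 2 (adjusted p = 1.73e-05), with no mutant above background. The esterases Ces3b and Pon1 fell by 3.42 ± 0.63 and 2.82 ± 0.36 (SE), and the mannose-binding lectin Mbl2 fell by 2.73 ± 0.39 (SE). Trp63 was 10.8-fold lower at day 0, where 2 of 3 mutants measured it, and at least 4.02-fold lower at day 2. Cyp2c37, Cyp2g1, Tmeff2 and Acnat2 fell by 2.23 to 2.70 log2 units. Cyp2e1, Inmt and Cyp2c54 fell by 3.47, 3.06 and 2.79 (adjusted p = 0.0464, 0.0221 and 0.0373) and passed in 11 of 25, 19 of 25 and 14 of 24 other settings.

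Of 39 secreted proteins and enzymes of hepatocytes, 20 fell and 19 did not pass, and 31 fell when adjusted over the list alone. Their mean was -0.68 (camera, adjusted p = 3.28e-12, and 0.158 with an estimated correlation), -0.61 and -0.88 within slides 1 and 2 and -0.67 with slide as a block. Tat, which degrades tyrosine, fell by 2.21 ± 0.21 (SE, adjusted p = 0.000172). Of 39 genes of xenobiotic metabolism, 22 fell, 1 rose and 16 did not pass (27 and 2 adjusted over the list alone), with a mean of -1.12 (adjusted p = 1.26e-08, and 0.162 with an estimated correlation). Of 28 genes of bile acid synthesis and transport, 10 fell and 18 did not pass (18 adjusted over the list alone), with a mean of -0.90 (adjusted p = 6.89e-08, and 0.158 with an estimated correlation). The bile acid ligase Slc27a5 and the uptake carrier Slc10a1 fell by 1.88 ± 0.26 and 1.38 ± 0.24 (SE). Cyp7a1, the first enzyme of bile acid synthesis, did not pass (-2.40 ± 0.81 SE, adjusted p = 0.0782). Of 22 hepatocyte transcription factors, 6 fell, 3 rose and 13 did not pass (9 and 3 adjusted over the list alone), with a mean of -0.42 (adjusted p = 0.0214, and 0.143 with an estimated correlation). Nr1i3, Tbx3 and Cebpa fell by 2.04, 1.37 and 0.64, and Hnf4a did not pass (-0.57 ± 0.20 SE, adjusted p = 0.0793).

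Metabolic and fetal genes moved too. Of 25 genes of gluconeogenesis and glycogen, 10 fell, 1 rose and 14 did not pass (11 and 1 adjusted over the list alone), with a mean of -0.48 (adjusted p = 0.000336, and 0.162 with an estimated correlation). Of 30 genes of fatty acid oxidation and ketogenesis, 10 fell and 20 did not pass (10 fell and 1 rose when adjusted over the list alone), with a mean of -0.51 (adjusted p = 0.000373, and 0.326 with an estimated correlation). Of 34 genes of fatty acid and cholesterol synthesis, 1 rose and 1 fell, neither when adjusted over the list alone, with a mean of -0.17 (adjusted p = 0.177). Of 30 fetal and imprinted growth genes, 10 rose, 1 fell and 19 did not pass (11 and 2 adjusted over the list alone), with a mean of 0.60 (adjusted p = 4.17e-05, and 0.0725 with an estimated correlation). The growth regulators Hmga2, Mycn and Mdk rose by 1.84 ± 0.16, 2.40 ± 0.24 and 2.56 ± 0.31 (SE). Igf2 fell by 0.45 ± 0.10 (SE, adjusted p = 0.0162), and Afp and H19 did not pass (-0.22 and -0.25, adjusted p = 0.259 and 0.16). The spots of Alb were saturated on all arrays, so its differences cannot be read.

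Markers of other cells in the newborn liver also differed between the genotypes. Of 35 erythroid genes, 18 fell and 17 did not pass, and 33 fell when adjusted over the list alone, with a mean of -0.93 (adjusted p = 3.28e-12, and 0.162 with an estimated correlation) and -0.90 and -0.89 within slides 1 and 2. Gata1, a transcription factor of red cell precursors, fell by 1.06 ± 0.17 (SE, adjusted p = 0.00307). Of 28 macrophage genes, 8 fell and 20 did not pass (9 adjusted over the list alone), with a mean of -0.45 (adjusted p = 2.97e-05, and 0.143 with an estimated correlation), -0.46 and -0.28 within the slides. Of 18 megakaryocyte genes, 4 fell and 14 did not pass (12 adjusted over the list alone), with a mean of -0.86 (adjusted p = 1.38e-05, and 0.449 with an estimated correlation), -0.80 and -1.48 within the slides. Of 23 granulocyte and monocyte precursor genes, 1 fell and 22 did not pass, and none passed when adjusted over the list alone, with a mean of -0.53 (adjusted p = 0.000429, and 0.494 with an estimated correlation), -0.52 and -0.997 within the slides. Of 49 stellate cell and matrix genes, 7 rose and 42 did not pass, both over all genes and when adjusted over the list alone, with a mean of 0.25 (adjusted p = 0.00469, and 0.494 with an estimated correlation), 0.21 and 0.048 within the slides. Without mutant day 0 replicate 3 that mean was 0.13 (adjusted p = 0.0813, against 0.000208 to 0.0813 over all 23 other settings).

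Of 42 cell cycle genes, 8 fell and 34 did not pass (12 adjusted over the list alone), with a mean of -0.32 (adjusted p = 1.38e-05, and 0.454 with an estimated correlation), -0.36 and -0.010 within slides 1 and 2. Of 24 targets of Wnt and Hippo-Yap signalling, 7 rose, 1 fell and 16 did not pass (8 and 2 adjusted over the list alone), with a mean of 0.38 (adjusted p = 0.0112, and 0.143 with an estimated correlation) and 0.24 after normexp treatment with the same scaling. Besides fatty acid and cholesterol synthesis, 6 further lists did not pass. They were lymphoid genes (none of 24 passed either way, with the lowest adjusted p of 0.0521 for Klrb1c, mean -0.37, adjusted p = 0.0971), endothelial genes (1 of 32 rose and 5 fell either way, -0.15, adjusted p = 0.201) and inflammation and acute phase genes (3 of 31 fell, 2 adjusted over the list alone, -0.075, adjusted p = 0.34). The others were stress and cell death genes (3 of 35 rose and 2 fell either way, 0.26, adjusted p = 0.159), pancreatic and intestinal genes (2 of 12 rose and 2 fell either way, 0.034, adjusted p = 0.826) and sex-linked genes (none of 5 passed either way, -1.91, adjusted p = 0.227). Of the 17 lists that passed camera, 16 passed in all 23 other settings with the preset correlation. None passed camera with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry called 13.

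Of 15945 genes tested, 1378 rose and 1066 fell over both days (limma), 711 and 292 of them at least 2-fold. At an unadjusted p under 0.05 there were 2231 and 2455, where chance alone gives 797 for both directions together. With slide as a block 1256 rose and 823 fell, and with pup sex as a covariate 690 and 321. Without day 0 control replicates 1 and 2 in turn, 858 and 849 rose and 444 and 397 fell. The falls numbered 654 and 594 without day 2 control replicates 1 and 2, 1929 without mutant day 0 replicate 3 and 570 without mutant day 2 replicate 2. Of 208 genes called without slide 1, 206 had the same direction on that slide, and of 247 called without slide 2, 245 had, against 57.7% and 56% of genes not called. In a fit of the authors' table, 2155 of 2443 of the called genes passed in the same direction.

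**Figure D2:**
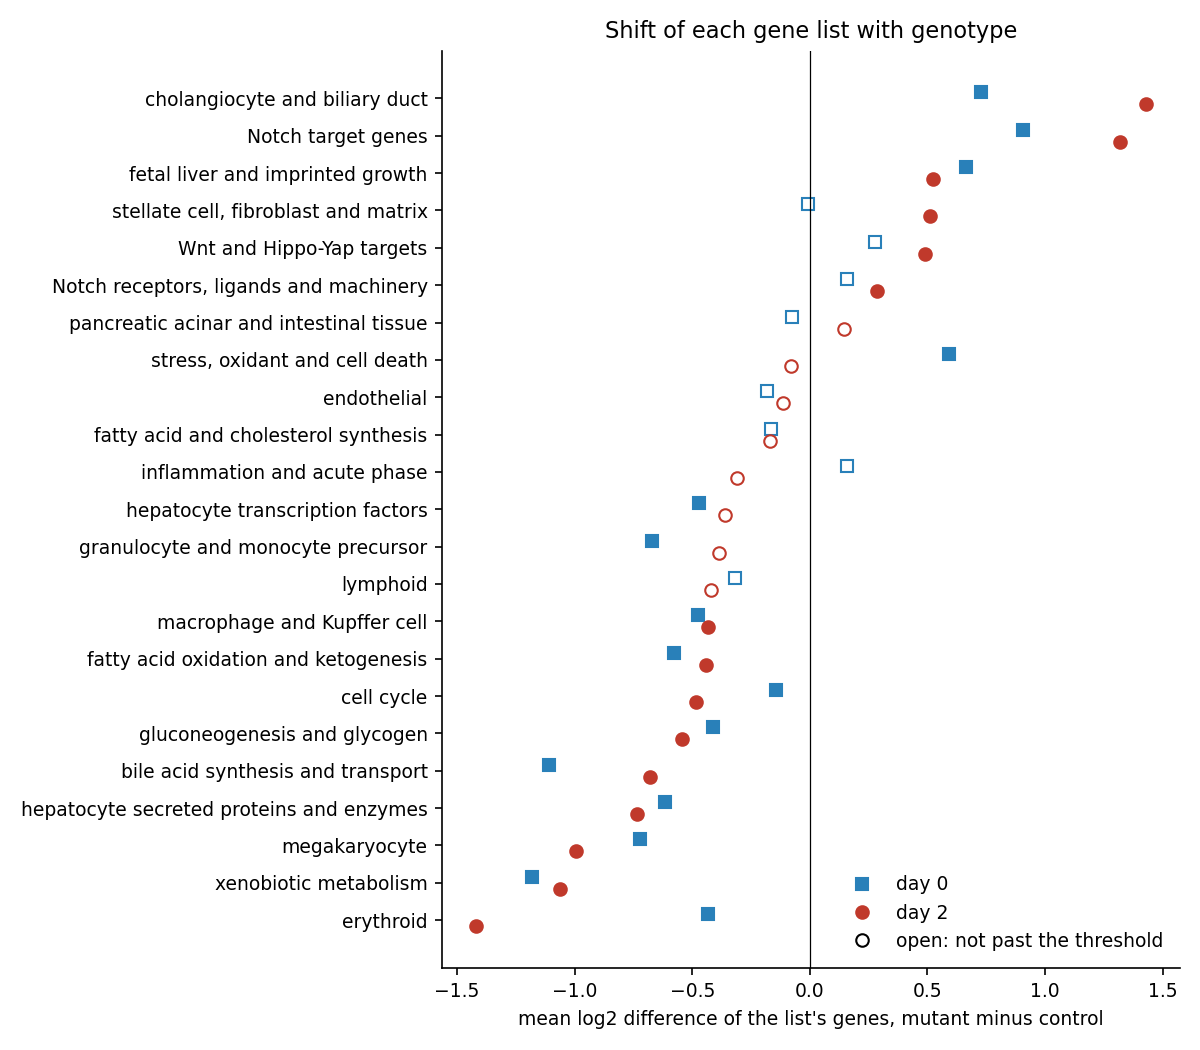
Mean log2 difference between mutants and controls of 23 gene lists at day 0 (squares, 3 mutants and 2 controls) and at day 2 (circles, 3 and 3), filled where camera passed at its preset correlation. Notch target and duct genes lay at 0.91 and 0.73 at day 0 and at 1.32 and 1.43 at day 2, and erythroid genes at -0.43 and -1.42.

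The second comparison asked how mutants differ from controls by the day of birth, in 3 mutants and 2 controls. Nrarp, Sox9 and Dcdc2a rose by 3.75 ± 0.30, 3.43 ± 0.28 and 3.42 ± 0.33 (SE), with adjusted p of 0.000719, 0.000719 and 0.00129. Hey1, Hes1, Spp1 and Epcam rose by 2.46, 2.04, 3.17 and 2.41. Heyl (1.16, adjusted p = 0.404), Krt19 (0.39, adjusted p = 0.796) and Krt7 (-0.27, adjusted p = 0.655) did not pass. The corticosteroid-binding globulin Serpina6 was 25.3-fold higher (4.66 ± 0.43 SE, adjusted p = 0.00129), and the neuropeptide receptor Vipr2 was at least 6.56-fold higher. Clec2h was at least 11.5-fold lower (adjusted p = 0.00108), and Cyp2c37 and Cyp4a14, which oxidise drugs and fatty acids, were 13.1-fold and 8.85-fold lower. Tat, Nr1i3, Slc27a5 and Slc10a1 fell by 2.18, 2.24, 2.11 and 1.88.

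At day 0 Notch targets had a mean difference of 0.91 (camera, adjusted p = 1.37e-05, and 0.147 with an estimated correlation), 1.14 and 0.42 within slides 1 and 2, with 6 of 23 past the threshold and 8 adjusted over the list alone. Duct genes had 0.73 (adjusted p = 1.43e-06, and 0.147 with an estimated correlation), 0.76 and 0.71 within the slides, with 9 of 37 higher, and 14 higher and 2 lower adjusted over the list alone. Hepatocyte proteins, xenobiotic metabolism and bile acid genes had means of -0.62, -1.18 and -1.11 (adjusted p of at most 6.94e-09, and 0.27, 0.216 and 0.147 with an estimated correlation), with 2, 5 and 2 genes lower. Within slides 1 and 2 the hepatocyte protein mean was -0.39 and -0.67 and the xenobiotic mean -0.77 and -0.99. Adjusted over the list alone 8, 20 and 14 were lower, and 4 xenobiotic genes were higher. Fetal genes had a mean of 0.67 (adjusted p = 2.16e-06, and 0.0536 with an estimated correlation). Macrophage, megakaryocyte, granulocyte and erythroid lists had means of -0.47, -0.72, -0.67 and -0.43 (adjusted p of at most 0.000528, and 0.147, 0.545, 0.485 and 0.545 with an estimated correlation). The erythroid mean was -0.40 within slide 1, 0.021 within slide 2, -0.19 without mutant day 0 replicate 3 and -0.22 with array weights. Within slides 1 and 2 the macrophage mean was -0.45 and -0.25, the megakaryocyte mean -0.84 and -1.77 and the granulocyte mean -0.76 and -1.50. The megakaryocyte mean was -0.28 without mutant day 0 replicate 2, where the list did not pass, and -1.31 without replicate 3. The granulocyte mean was -0.42 and -1.13 without these arrays, and -1.01 and -0.33 without day 0 control replicates 1 and 2. Array weights gave -1.24 for megakaryocyte and -1.07 for granulocyte genes. Hepatocyte transcription factors, gluconeogenesis, and fatty acid oxidation had means of -0.47, -0.41 and -0.58 (adjusted p of at most 0.0117, and 0.147, 0.29 and 0.327 with an estimated correlation), and sex-linked genes also passed (adjusted p = 0.038, and 0.311 with an estimated correlation). The fatty acid oxidation mean was -0.38 and -0.65 within the slides. The gluconeogenesis mean was -0.25 for genes well above background on all 11 arrays. The sex-linked list had means of -1.26, -1.35 and -1.88 with the normexp scalings and in the authors' table, and did not pass with array weights or with sex as a covariate (0.14). It also did not pass without day 0 control replicate 1 or without any 1 of the day 0 mutants, with means from -3.75 to -3.55.

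The other 2 of the 16 lists that passed at day 0 rested on mutant day 0 replicate 3. Stress and cell death genes had a mean of 0.59 (adjusted p = 0.0183, and 0.604 with an estimated correlation), but -0.27 and -0.13 within slides 1 and 2 and -0.20 without that array. That mean was 0.984 and 0.983 without mutant day 0 replicates 1 and 2, and 0.52, not past the threshold, without day 0 control replicate 2. It did not pass with slide as a block (0.29) or with array weights (-0.092). Cell cycle genes had a mean of -0.15 (adjusted p = 0.0457, and 0.705 with an estimated correlation) and 0.021 without that array, and -0.126 and 0.168 within slides 1 and 2. The list did not pass with slide as a block (-0.070), with sex as a covariate (-0.13), with array weights or for genes well above background on all 11 arrays. That mean was -0.071 and -0.22 without day 0 control replicates 1 and 2, the first not past the threshold, -0.265 without mutant day 0 replicate 2, and -0.145, not past the threshold, without day 2 control replicate 3. None of the lists passed camera with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry called 9.

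At day 0, 241 genes rose and 101 fell (limma), with 1239 and 1094 at an unadjusted p under 0.05. With slide as a block 180 rose and 69 fell. Normexp followed by quantile scaling changed the share of called genes that were higher from 70.5% to 59.7%. With pup sex as a covariate 22 rose and 7 fell, with Sox9, Nrarp and Clec2h among them. Without day 0 control replicates 1 and 2 in turn, 61 and 50 rose and 20 and 6 fell. The rises numbered 139 without mutant day 0 replicate 1, 486 without replicate 3 and 156 without mutant day 2 replicate 1. The falls numbered 48, 65 and 348 without mutant day 0 replicates 1, 2 and 3, 64 and 64 without day 2 control replicates 1 and 2, and 60 without mutant day 2 replicate 1. No gene was called without slide 1 or slide 2, so directions could not be checked on a slide left out.

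The third comparison asked the same question on day 2, in 3 mutants and 3 controls. Sox9 was 35.7-fold higher (5.16 ± 0.25 SE, adjusted p = 1.18e-05), and Nrarp, Hey1 and Heyl rose by 3.83 ± 0.27, 3.74 ± 0.35 and 3.54 ± 0.53 (SE). Ddr1 and Epcam rose by 4.16 ± 0.19 (SE) and 4.52, and Krt19 and Krt7 by 2.68 ± 0.53 and 1.82 ± 0.22 (SE). Igfbpl1, which resembles an insulin-like growth factor binding protein (chromosome 4, 45831031 to 45831090), was at least 22.4-fold higher (adjusted p = 2.01e-05), and Dpysl4 at least 29.5-fold. The signalling protein Wnt10a (chromosome 1, 74737266 to 74737325) was at least 17.3-fold lower (adjusted p = 0.00011), the methyltransferase Mettl7b was 14.5-fold lower, and the chemokine Cxcl9 at least 8.33-fold lower. The noncoding transcript Gt(ROSA)26Sor at the Rosa26 locus was at least 17.8-fold lower (adjusted p = 0.0135). The embryonic globin Hbb-bh1 and Gata1 fell by 2.30 ± 0.27 and 1.54 ± 0.22 (SE).

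On day 2 Notch targets had a mean of 1.32 (camera, adjusted p = 8.34e-07, and 0.155 with an estimated correlation), 1.27, 1.20 and 1.49 within slides 1, 2 and 3, with 12 of 23 higher both over all genes and adjusted over the list alone. Duct genes had a mean of 1.43 (adjusted p = 8.41e-10, and 0.134 with an estimated correlation), 1.45, 1.18 and 1.66 within the slides, with 22 of 37 higher and 3 lower, and 24 and 4 adjusted over the list alone. Erythroid genes had a mean of -1.42 (adjusted p = 1.04e-13, and 0.245 with an estimated correlation), -1.40, -1.81 and -1.06 within the slides, with 22 of 35 lower, and all 35 lower adjusted over the list alone. Hepatocyte proteins had a mean of -0.74 (adjusted p = 4.34e-10, and 0.245 with an estimated correlation), -0.83, -1.08 and -0.295 within the slides and -0.38 with normexp and quantile scaling, with 21 of 39 lower, and 27 adjusted over the list alone. Stellate cell and matrix genes had 0.51 (adjusted p = 7.74e-05, and 0.401 with an estimated correlation), 0.699, 0.32 and 0.51 within the slides, with 14 of 49 higher and 1 lower (16 and 5 adjusted over the list alone), and cell cycle genes had -0.49 (adjusted p = 3.14e-06, and 0.425 with an estimated correlation), -0.59, -0.19 and -0.67 within the slides and -0.29 with normexp and quantile scaling, with 13 of 42 lower (20 adjusted over the list alone). Xenobiotic, bile acid, gluconeogenesis, macrophage and megakaryocyte lists had means of -1.06, -0.68, -0.54, -0.43 and -0.996 (adjusted p of at most 0.00206, and 0.3, 0.375, 0.286, 0.26 and 0.491 with an estimated correlation). The xenobiotic mean was -0.99, -1.73 and -0.47 within the slides, the bile acid mean was -0.65, -1.07 and -0.32, and the gluconeogenesis mean was -0.49, -0.87 and -0.27 within them and -0.25 with normexp and quantile scaling. Fetal genes, the Notch pathway and Wnt and Hippo-Yap targets had 0.53, 0.29 and 0.49 (adjusted p of at most 0.0051, and 0.155, 0.245 and 0.155 with an estimated correlation), the last 2 0.15 and 0.32 after normexp treatment with the 75th percentile. Fatty acid oxidation had -0.44 (adjusted p = 0.0124, 0.491 with an estimated correlation, and from 0.00231 to 0.625 over 23 other settings, 17 of which passed), with -0.36 and -0.32 without day 2 control replicate 3 and mutant day 2 replicate 1, neither past the threshold. It was -0.15 with normexp and quantile scaling and did not pass under either quantile scaling, in the authors' table or after normexp treatment with the 75th percentile. None of the 15 lists passed camera with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry called 14.

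On day 2, 1504 genes rose and 1012 fell (limma), with 2329 and 2492 at an unadjusted p under 0.05, and 1420 and 899 with slide as a block. Over all genes tested the median difference was -0.096, and -0.14 after normexp treatment with the same scaling. Without mutant day 0 replicate 3, 2317 rose and 2320 fell. Without mutant day 2 replicate 2, 972 rose and 373 fell. The falls numbered 408 and 451 without day 2 control replicates 1 and 2, and 543 and 552 without mutant day 2 replicates 1 and 3. Of the genes called without slide 1, 2 or 3, 260 of 262, 281 of 284 and 3348 of 3556 had the same direction on the slide left out, against 68.2%, 63% and 57.4% of genes not called. The days share no arrays. Of the 241 rises at day 0, 217 also rose on day 2, against 22.7 if calls on the 2 days were independent. Of the 101 falls at day 0, 54 fell again, against 6.41 if independent, and 1 rose. Both contrasts share each gene's estimate of the spread, so the calls are not fully independent and these expected numbers may be too low.

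**Figure D3:**
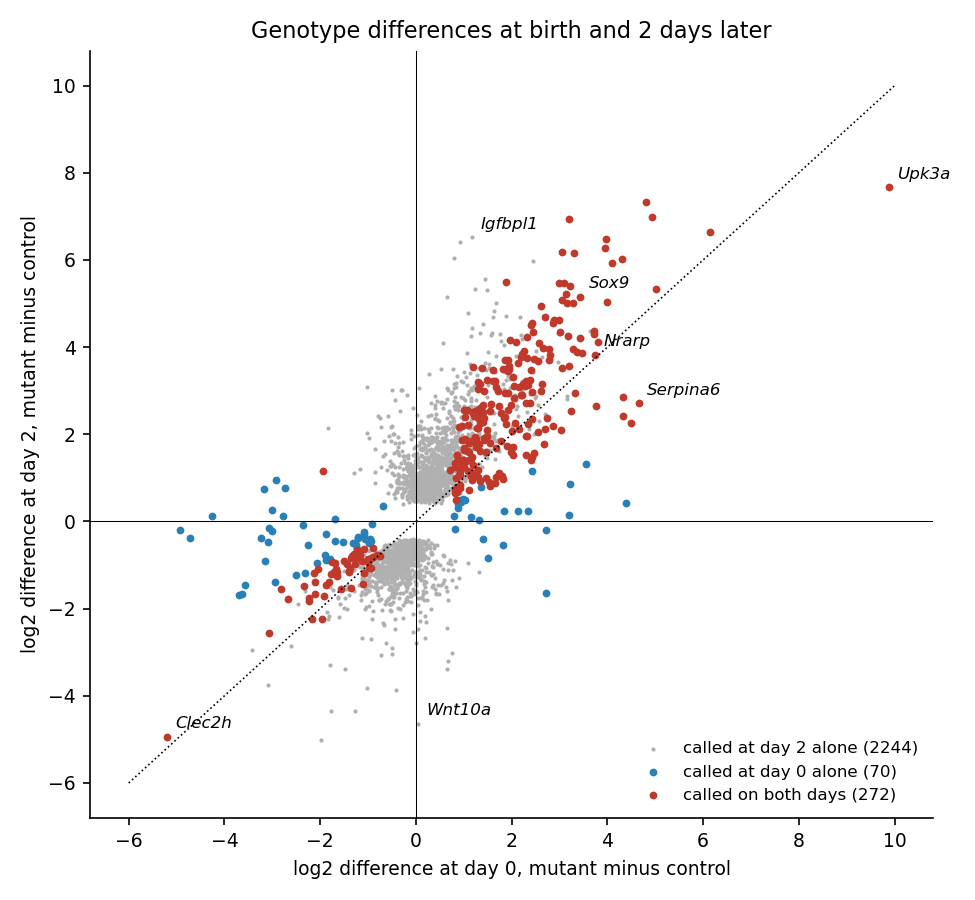
Fitted log2 difference between mutants and controls at day 0 (horizontal) and at day 2 (vertical) of each gene past the threshold on day 2 alone (grey), day 0 alone (blue) or both days (red), with a dotted line where both differences are equal. The 217 genes that rose on both days had median differences of 1.91 at day 0 and 2.53 at day 2. The 54 genes that fell on both days had medians of -1.4 and -1.09.

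The fourth comparison asked whether the difference between mutants and controls was itself different on the 2 days. For Nrarp and Sox9 the change between days was 0.077 and 1.72 (adjusted p = 0.953 and 0.108), and for Hey1 and Heyl it was 1.27 and 2.38 (adjusted p = 0.311 and 0.238), none past the threshold. For Ddr1 and Krt7 it was 2.19 ± 0.28 and 2.09 ± 0.34 (SE, adjusted p = 0.0241 and 0.0489), and they passed in 12 and 8 of 23 other settings. For the growth factor Tgfb2 it was 2.52 ± 0.24 (SE, adjusted p = 0.00862). Duct genes differed more on day 2, by a mean of 0.71 (camera, adjusted p = 5.59e-05, and 0.406 with an estimated correlation), 0.70 and 0.47 within slides 1 and 2, with 2 of 37 past the threshold and 9 adjusted over the list alone. Stellate cell and matrix genes had a mean of 0.52 (adjusted p = 6.25e-05, and 0.611 with an estimated correlation), 0.97 and 0.55 within the slides, with 1 of 49 past the threshold and 4 adjusted over the list alone, and 0.34 with sex as a covariate and 0.78 with array weights. Erythroid genes had -0.99 (adjusted p = 8.7e-09, and 0.611 with an estimated correlation), -1 and -1.83 within the slides, with 1 of 35 lower adjusted over the list alone. Notch targets had 0.41 (adjusted p = 0.0358, 0.611 with an estimated correlation, and from 0.00106 to 0.303 over 23 other settings), and Wnt and Hippo-Yap targets 0.21 (adjusted p = 0.0358, 0.406 with an estimated correlation, and from 0.00292 to 0.144 over 23 other settings). The Notch target mean was 0.13 and 0.79 within slides 1 and 2. It was 0.66 and 0.17 without day 0 control replicates 1 and 2, 0.31 without day 2 control replicate 3, 0.29 without mutant day 0 replicate 2 and 0.41 without mutant day 2 replicate 1, and all but the first no longer passed. Nor did it pass under either quantile scaling, in the authors' table or with the mean over a gene's probes. The Wnt and Hippo-Yap mean was 0.11, 0.23 and 0.20 without day 0 control replicate 1, day 2 control replicate 2 and mutant day 2 replicate 1, none past the threshold, and 0.12 without mutant day 0 replicate 3. It was 0.24 and 0.0015 within slides 1 and 2, 0.399 for genes well above background on all 11 arrays and 0.13 with array weights. The list did not pass with slide as a block (0.18), with sex as a covariate (0.20), with the mean over a gene's probes (0.14), under either quantile scaling or in the authors' table. Cell cycle genes had -0.34 (adjusted p = 0.000489, 0.904 with an estimated correlation, and from 1.97e-08 to 0.101 over 23 other settings, 20 of which passed), and -0.22 without mutant day 0 replicate 2. It was -0.13 and -0.135 under the quantile scalings and -0.16 in the authors' table, none past the threshold. These 6 lists were the only ones past camera, where none passed with an estimated correlation and 2 had an unadjusted p under 0.05. Fry called 0 lists and its mixed test 4.

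For 37 genes the signed difference, mutant minus control, was larger on day 2 and for 6 it was smaller (limma), with 1245 and 1020 at an unadjusted p under 0.05. Larger and smaller in these counts give the sign of the change between days, not the size of the difference. In the same sense 12 were larger and 0 smaller with slide as a block, while the fit without it had 6 smaller. Without day 0 control replicates 1 and 2 in turn, 6 and 1 were larger and 0 and 1 smaller. Without day 2 control replicates 1, 2 and 3 these were 6, 7 and 7 larger and 0, 1 and 2 smaller. Without mutant day 0 replicates 1, 2 and 3 there were 60, 9 and 195 larger, with 2 smaller without replicate 2 and 48 without replicate 3. Without mutant day 2 replicates 1, 2 and 3 there were 7, 7 and 10 larger and 0, 0 and 2 smaller.

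The fifth comparison asked how the normal liver changes between birth and day 2, in 3 and 2 controls. Both day 0 controls were male and 2 of the 3 day 2 controls were female, so age and sex partly coincide here. Mettl7b (chromosome 10, 128361560 to 128361619) was 143-fold higher on day 2 (7.16 ± 0.40 SE, adjusted p = 7.11e-05), and the sulfotransferase Sult1c2 was 110-fold higher. Cyp1a2, a cytochrome of drug metabolism, was 66.6-fold higher, with 1 of 2 day 0 controls above background. The protease inhibitor A2m was 30.8-fold lower (-4.95 ± 0.21 SE, adjusted p = 2.18e-05), and the imprinted gene Dlk1 fell by 2.24 ± 0.26 (SE). Tat rose by 2.78 ± 0.31 (SE), Nrarp rose by 1.65 ± 0.30 (SE, adjusted p = 0.0124) and Sox9 fell by 1.87 ± 0.28 (SE, adjusted p = 0.00612).

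Fatty acid oxidation rose in controls by a mean of 1.20 (camera, adjusted p = 5.07e-11, and 0.582 with an estimated correlation), 1.08 and 1.16 within slides 1 and 2, with 15 of 30 higher and 19 adjusted over the list alone. Fatty acid and cholesterol synthesis fell by 1.05 (adjusted p = 2.84e-06, and 0.582 with an estimated correlation), with 12 of 34 lower and 18 adjusted over the list alone, Scd1 by 3.77 ± 0.57 (SE). Granulocyte and monocyte precursor genes fell by 1.32 (adjusted p = 6.68e-08, and 0.582 with an estimated correlation), with 9 of 23 lower and 16 adjusted over the list alone. Xenobiotic, bile acid and cell cycle genes had means of 1.02, 0.50 and 0.37, and macrophage, stellate, erythroid and endothelial genes had -0.43, -0.53, -0.45 and -0.28 (adjusted p of at most 0.0418, and 0.582 with an estimated correlation, or 0.621 for erythroid genes). The erythroid mean was -0.35, -0.42 and -0.39 without day 0 control replicate 1 and day 2 control replicates 2 and 3, and the endothelial mean was -0.23 and -0.21 without day 0 control replicate 2 and day 2 control replicate 3, none past the threshold. The endothelial mean was -0.185 and -0.24 within slides 1 and 2. With pup sex as a covariate the erythroid and endothelial means were -0.41 and -0.298, neither past the threshold. The bile acid mean was 0.31 with normexp and quantile scaling, and the cell cycle mean was 0.18 under both quantile scalings and 0.20 in the authors' table. None of the 10 lists passed camera with an estimated correlation, where 1 had an unadjusted p under 0.05, and fry called 3.

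In controls 819 genes rose and 870 fell (limma), with 2312 and 2325 at an unadjusted p under 0.05, 600 and 614 with slide as a block and 124 and 158 with pup sex as a covariate. Without day 0 control replicates 1 and 2 in turn, 102 and 106 rose and 146 and 103 fell. Without day 2 control replicates 1, 2 and 3, 477, 249 and 380 rose and 493, 334 and 424 fell. Without mutant day 0 replicate 3, 2104 rose and 2093 fell, and without mutant day 2 replicate 3, 527 rose. Of the genes called without slide 2, all 3 had the same direction on it, and none was called without slide 1.

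The last comparison asked how the mutant liver changes over the same days, in 3 and 3 mutants. All day 0 mutants were female and 1 of the 3 day 2 mutants was male, so sex was uneven here too. The lubricating proteoglycan Prg4 (chromosome 1, 152212251 to 152212991) was at least 20.8-fold higher on day 2 (adjusted p = 9.61e-05), and Apoa4 and Cyp3a25 were 55.1-fold and 45.9-fold higher. Cyp4a14 and Ehhadh, enzymes of fatty acid oxidation, rose by 5.30 ± 0.36 and 3.24 ± 0.24 (SE). Hbb-bh1 fell by 3.60 ± 0.27 (SE, adjusted p = 0.000223), and the stress-induced Nupr1 and the glycogen regulator Ppp1r3c were 21.1-fold and 20.7-fold lower. Clu, which duct cells make, rose by 2.08 ± 0.24 (SE).

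Fatty acid oxidation rose in mutants by a mean of 1.34 (camera, adjusted p = 9.69e-11, and 0.322 with an estimated correlation), 0.97, 1.40 and 1.64 within slides 1, 2 and 3, with 19 of 30 higher and 21 adjusted over the list alone. Duct, xenobiotic and bile acid genes had means of 0.61, 1.14 and 0.92 (adjusted p of at most 0.000488, and 0.406, 0.487 and 0.426 with an estimated correlation). Within slides 1, 2 and 3 the xenobiotic mean was 0.85, 0.48 and 2.08 and the bile acid mean 0.65, 0.43 and 1.68, so both were largest on slide 3, which holds mutant day 0 replicate 3. Erythroid genes fell by 1.45 (adjusted p = 2.99e-10, and 0.426 with an estimated correlation), -1.37, -2.25 and -0.73 within the slides, with 18 of 35 lower and 1 higher, and 21 and 1 adjusted over the list alone. Fatty acid and cholesterol synthesis, granulocyte and macrophage genes had -1.05, -1.04 and -0.39 (adjusted p of at most 0.00161, and 0.431, 0.525 and 0.426 with an estimated correlation). The mean of fatty acid and cholesterol synthesis was -1.27, -1.33 and -0.56 within the slides. The granulocyte mean was -0.52, -0.58 and -2.02 within slides 1, 2 and 3 and -0.57 without mutant day 0 replicate 3, and it was also more than 1.5 times smaller with array weights. Fetal and gluconeogenesis genes had -0.49 and -0.71 (adjusted p = 0.00378 and 0.011, and 0.322 and 0.431 with an estimated correlation), and gluconeogenesis genes did not pass after normexp treatment with the 75th percentile (-0.59). Inflammation genes had -0.88 (adjusted p = 0.0077, and 0.54 with an estimated correlation), -0.15, -0.19 and -2.28 within slides 1, 2 and 3, and -0.20 without mutant day 0 replicate 3 (adjusted p = 0.566, against 0.000675 to 0.566 over 23 other settings), and did not pass with array weights (-0.28). None of the 11 lists passed camera with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry called 9.

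In mutants 1439 genes rose and 1748 fell (limma), with 2845 and 3166 at an unadjusted p under 0.05, and 1273 and 1716 with slide as a block. More genes rose than fell under quantile scaling (1605 and 1472), with normexp and quantile scaling (1699 and 1396) and in the authors' table (1645 and 1432), while normexp treatment with the 75th percentile gave 1536 and 2638, so which direction prevailed rests on the scaling. Without mutant day 2 replicates 1, 2 and 3 in turn, 794, 659 and 592 rose and 999, 862 and 725 fell. Of the genes called without slide 1, 2 or 3, 159 of 161, 9 of 9 and 2095 of 2448 had the same direction on the slide left out.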

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

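All tests in this part were chosen before the results were seen. Each result below stands out because the difference between mutants and controls was itself different on day 0 and day 2, by the test of that difference in limma for genes and in camera for lists. In all, the signed difference, mutant minus control, was larger on day 2 for 37 genes and smaller for 6. These counts give the sign of the change, so a fall that deepened is among the 6. For Igfbpl1, Lrrn1, Ctnna2, Wnt10a and Fam155a the fitted change takes in groups not above background, so its size cannot be read and the bounds on the folds are given beside it.

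C2cd4b, a nuclear protein induced by inflammation, was 1.74-fold higher in mutants at day 0 and 66.3-fold higher on day 2, a change of 5.25 ± 0.53 (SE, adjusted p = 0.00874). Rgma, a guidance molecule and BMP co-receptor, was 2.72-fold and 47-fold higher (4.11 ± 0.53 SE). Igfbpl1 was not above background in either genotype at day 0 and was at least 22.4-fold higher on day 2 (fitted change 5.36). Lrrn1 was 1.56-fold and at least 20.6-fold higher (4.51), and Ctnna2, a catenin, at least 1.27-fold and at least 18.1-fold higher (3.61). Scrn1 was 1.35-fold lower at day 0 and 6.91-fold higher on day 2 (3.22 ± 0.24 SE, adjusted p = 0.00256), and was the only one of these genes past the threshold in all 23 other settings. Cpsf4l was 3.56-fold lower and then 4.42-fold higher (3.98), and Trim6 was 7.61-fold lower and then 1.93-fold higher (3.88).

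Wnt10a was above background in neither genotype at day 0 and was at least 17.3-fold lower in mutants on day 2, with a fitted change of -4.68 (adjusted p = 0.0241). Mettl7b was 1.34-fold lower at day 0 and 14.5-fold lower on day 2 (-3.44). Fam155a was 1.59-fold higher and then at least 6.52-fold lower (-3.87), Abhd1 was 6.63-fold higher and then 1.15-fold lower (-2.93), and Lkaaear1 was 1.76-fold higher and then 1.88-fold lower (-1.73). Crym, a thyroid hormone binding protein, was 5.06-fold higher at day 0 and 1.17-fold higher on day 2 (-2.11 ± 0.30 SE). Except for Scrn1, these genes passed in 4 to 19 of the other settings.

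Among the lists, the difference was larger on day 2 for duct genes (0.71), stellate cell and matrix genes (0.52), Notch targets (0.41) and Wnt and Hippo-Yap targets (0.21), and more negative for erythroid genes (-0.99) and cell cycle genes (-0.34). Sex and genotype coincided at day 0, and no list passed with a correlation estimated from the data. With slide as a block and with sex as a covariate the means of duct genes (0.67 and 0.82), stellate cell genes (0.58 and 0.34), Notch targets (0.42 and 0.56), erythroid genes (-1.06 in both) and cell cycle genes (-0.415 and -0.36) stayed past the threshold, and that of Wnt and Hippo-Yap targets (0.18 and 0.20) did not. With the block the signed difference was larger on day 2 for 12 genes and smaller for 0. Array position coincides with group on every slide and could not be tested.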

How the results depend on the processing

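No test in this part was chosen after the result was seen. Of 3306 values of lists under other settings, 3043 kept their direction and side of the threshold, as did 16195 of 18183 values of named genes. Among the rest 51 and 1488 no longer passed, 102 and 360 newly passed, 106 and 133 that had not passed changed sign, and 4 and 7 that had passed changed sign. Signal over background limits genes near background, whose folds are bounds.

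Array weights, which gave mutant day 0 replicate 3 a weight of 0.122 and the others 0.627 to 1.66, raised the counts of higher and lower genes to 2197 and 2294 over both days, 687 and 497 at day 0, 2329 and 2641 at day 2, 279 and 87 for the difference between days, and 2455 and 2285 for age in controls. Pup sex as a covariate lowered them to 690 and 321, 22 and 7, 4 and 1 (difference between days), 124 and 158 (age in controls) and 860 and 1030 (age in mutants). Without a day term 759 and 317 passed over both days. The compared groups alone gave 40 and 21 at day 0, 1731 lower at day 2, and 664 and 1035 for age in mutants. Without a filter on dim probes 57 were lower at day 0 and 523 higher with age in controls. Larger and smaller signed differences on day 2 then numbered 15 and 2. These numbered 16 and 3 with quantile scaling. Smaller ones numbered 3 with the filter on all 11 arrays and 10 with the trended prior. Normexp with the 75th percentile gave 2638 lower with age in mutants. Fewer arrays, fewer degrees of freedom or more genes tested are part of several of these settings; otherwise the cause was not tested.

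The arrays of 1 replicate number share a slide, and the labels give no litters. With this replicate block the signed difference between genotypes was larger on day 2 for 12 genes and smaller for 0, while the other counts stayed within 1.5 times. In the day 2 comparison, where the numbers pair the arrays, the block changed the call of no list. Elsewhere cell cycle and stress genes at day 0 and Wnt and Hippo-Yap targets between days no longer passed with it. Endothelial genes at day 0 (-0.20), granulocyte genes between days (0.42), and gluconeogenesis and inflammation genes with age in controls (-0.64 and -0.59) newly passed, and no other list changed its call. Residuals of the genes correlated above 0.1 in 5 of 15 pairs of arrays with the same number (-0.0447 to 0.294, median 0.0753). Of the pairs with different numbers, 1 of 30 did (median -0.0264). Residuals cancel within each group, so the pairs with different numbers are tied to the others and are no separate baseline. The mean correlation within slides was 0.0245.

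Lists past camera fell to 0 in all 6 contrasts with an estimated correlation. Fry called 9 at day 0, 0 for the difference between days (4 in its mixed test) and 3 for age in controls. Without the filter on dim probes 10 lists passed between days.

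Leaving out each array in turn gave 849 to 2046 higher and 397 to 1929 lower genes over both days, 50 to 486 and 6 to 348 at day 0, 972 to 2317 and 373 to 2320 at day 2, 1 to 195 and 0 to 48 for the difference between days, 102 to 2104 and 103 to 2093 for age in controls, and 592 to 1558 and 725 to 1872 for age in mutants. The lists ranged from 17 to 19, 15 to 16, 15 to 16, 4 to 11, 9 to 11 and 11 to 13. Where an array left 1 day 0 control, it was assumed to vary like the other groups. Mutant day 0 replicate 3 gave the highest counts of both-day, day 0, day 2, day-difference and control-age genes when left out. At day 2 and for age in controls it belongs to neither group compared. The fitted differences there did not change without it (Notch targets 1.32 at day 2 either way). The higher counts in these contrasts came through the shared estimate of the spread.

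Among values past the threshold, these changed sign. At day 0 cell cycle genes went to 0.021 without mutant day 0 replicate 3 (-0.265 to 0.021 over single arrays left out), stress genes to -0.092 with array weights and -0.20 without that replicate (-0.20 to 0.984), and sex-linked genes to 0.14 with the sex covariate. With quantile scaling and with normexp and quantile scaling, Afp at day 2 went to 0.034 and 0.066, and Afp with age in mutants to 0.018 and 0.082. Alb with age in mutants went to 0.17 and 0.025, which cannot be read as its spots were saturated. Fabp1 at day 2 went to 0.012 with normexp and quantile scaling. The cause was not tested.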

Other observations

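The tests of the Gt(ROSA)26Sor pattern for the loss of 1 of 2 active copies and for the wider region, the sizes and errors with sex as a covariate, and the splits that part the day 2 pairs were chosen after the result was seen, and the other tests here before. Outside the lists that passed, single genes differed between the genotypes over both days. The villus protein Vil1 rose by 1.79 ± 0.25 (SE), and the secreted lectin Reg1 was at least 3.41-fold higher at day 0 and 14.9-fold higher at day 2, while Tff3, a trefoil peptide, and the amylase Amy2a5 fell by 1.79 ± 0.29 and 1.33 ± 0.24 (SE). The plasma proteins Apcs and Itih4 fell by 1.44 ± 0.15 and 1.19 ± 0.19 (SE). Gclc, which limits glutathione synthesis, rose by 1.07 ± 0.11 (SE, adjusted p = 0.000232). In lipid synthesis Me1 rose by 1.46 ± 0.38 and Thrsp fell by 1.94 ± 0.48 (SE).

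Among the stromal and vascular genes, the intermediate filament Vim, the matrix protein Fbln1 and the neurotrophin receptor Ngfr rose by 0.99 ± 0.15, 1.42 ± 0.22 and 1.80 ± 0.29 (SE) over both days. The clotting factor F8 fell by 1.08 ± 0.15 (SE) and the endothelial mucin Emcn rose by 0.58 ± 0.14 (SE). Among proliferation genes Cdc6 and Mki67 fell by 0.74 ± 0.14 and 0.54 ± 0.11 (SE). With age in controls Ehhadh rose by 2.59 ± 0.27 (SE), and Fdps, of cholesterol synthesis, fell by 2.87.

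Mutant day 0 replicate 3 had 1074 genes at least 2-fold outside all other arrays. The scaling of that array would be undone by quantile normalization, yet 92.1% of these genes stayed outside after it, and 72% were outside in the authors' table. A low signal can also change the order of genes within an array, which quantile normalization keeps. It therefore stays open. A fault of slide 3 would show on its other arrays, where the median departure of these genes in the same direction was at most -0.063, against 1.83 on the array itself. The stress genes Hspa1a and Ddit3 (4.75 and 2.49 there, at most -1.59 and -1.14 elsewhere) and the neighbours Pdia3, Catsper2 and Ppip5k1 on chromosome 2 (-5.26, -8.04 and -8.06 there, at least 3.23, -2.88 and -3.65 elsewhere) were chosen after their values were seen. The condition of that pup or of its RNA may account for part of the pattern and was not tested. Why these neighbours on chromosome 2 fell together on that array alone was not tested either.

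Gt(ROSA)26Sor was near background in all 6 mutants and in day 0 control replicate 1 (-8.17), while the other 4 controls lay from -2.87 to -1.86. A mislabelled control would lie with the mutants, but over 2504 genes called at day 2 that array lay at 0.116 of the way from the other day 0 control to the day 0 mutants. Loss of signal from 1 of 2 active copies would give a gap near 1 log2 unit, and the smallest gap was 3.45. Its neighbours Setd5 and Thumpd3 differed by 0.275 and 0.204, so the wider region did not lose signal. Modified Rosa26 alleles on both copies in those pups may account for it, as the labels do not give the copy number, and this stays open.

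At day 0 both controls were male and all mutants female. At day 2, where each genotype had 1 male and 2 females, the genotype difference had the same direction for 323 of 337 day 0 calls that were not sex-linked, with a median of 1.69 against 1.78 at day 0. Females differed from males within a genotype at day 2 by at most 0.0554 of the day 0 size in the direction of the calls, though each of these differences rests on a single male. Pup sex is therefore unlikely to be behind the calls as a set. With sex as a covariate all 337 kept their direction, and their median size was 1.70 with a median SE of 0.389, against 1.78 and 0.273 without it. Only 25 of them still passed, mostly through the larger error. Sex varies within groups at day 2 alone, so this fit adds no separate evidence on sex at day 0. For single genes an effect of sex stays open, because sex and genotype coincided at day 0. At day 2, 111 of the 337 differed in the direction of the call in females of both genotypes.

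Other splits of the arrays within days into groups of the same sizes were tried for the results with at least 3 arrays on each side. Over both days 1 of 100 splits drawn from 200, the real one, called as many genes (2444 against 2151 at most in the others). Chance alone is therefore unlikely to give that count. As the numbers pair the day 2 arrays, all 80 splits that part the 3 day 2 pairs were also run, and 32 of these exchange arrays only within slides on both days. The real split alone called as many genes in both sets (2444 against 2151 at most), so chance alone is unlikely there too. The smallest share that the smaller set can give is 1 of 32. The splits with 2151 and 2126 genes set all 5 controls and 1 day 0 mutant against the other 5 mutants, and so nearly repeat the real one. For the lists 8 of 100 splits passed as many (17 against 18 at most), and 6 of the 80 and 4 of the 32 did, so chance is not excluded. The median over the other splits was 10 lists over both days, 9 at day 2 and 11 for age in mutants. At day 2 and for age in mutants the 10 splits are too few for a share under 0.05. The real and highest other counts were 2516 and 0 genes and 15 and 13 lists at day 2, where 1 split gave as many in each case, and 3187 and 1 genes and 11 and 15 lists for age in mutants, where 1 and 8 splits did.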
